A study of Drosophila melanogaster with 9 samples.

How the data were processed

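H3K27me3 was measured by chromatin immunoprecipitation and sequencing in Drosophila melanogaster larvae of the third instar, grown at 25 °C per the labels, with chromatin fixed in 1% formaldehyde and quenched in 0.125 M glycine. The 9 samples were 6 immunoprecipitated libraries and 3 inputs. The 6 libraries fell into 3 groups of 2 by the sample titles: wild-type males, males with deletions of roX1 and roX2, and wild-type females. The inputs were not used here.

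The submitters' processing notes name Trimmomatic 0.39, Bowtie2 2.4.5, SAMtools 1.13, Picard and deepTools 3.5.1 and the genome build dm6. The peak caller, its settings and the use made of the inputs are not given in the sources used here. Each library has its own deposited broad peak list, so peaks were called per sample and replicates were not pooled. In each list the authors give a display score per peak, a fold enrichment per peak (a ratio of signal over background), and −log10 p and −log10 q values; these deposited −log10 values, the score and the fold are the authors' own numbers. All deposited peaks had a −log10 q of at least 1, that is q of at most 0.1. Folds were used only to rank or filter peaks within a list and were not compared between lists. The lists hold no read counts, so the depth per sample is unknown, no interval from counts can be given, and a difference in depth between libraries can change how many weak peaks were called.

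Peaks of each library were merged and their covered bases computed on X, 2L, 2R, 3L, 3R and 4. The share of an arm is relative to its span up to the last annotated gene or peak (23.5 Mb for X), since no sequence lengths were used here. The gene table was that of the Release 6 assembly, the same coordinates as dm6, with 13922 protein-coding genes on these arms and no strand. A gene was marked in a library when at least 50% of its body was covered. In each comparison a gene lost the mark when it was marked in both libraries of the reference group and in neither of the other, and gained it in the opposite case; this rule gives no p-value, and its count was set beside the other 2 splits of the 4 libraries. Shares of lost or gained genes on X and on the large autosomal arms were compared with Fisher's exact test (two-sided), among genes that could have been lost or gained. Genes of 1 domain are not independent, so 1 gene per 100 kb was an alternative. Library values were compared with exact permutation tests (two-sided). Wide domains were compared by a permutation test with 100000 permutations.

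The tests, the 25 gene lists and the alternatives were fixed before the data were examined, except where the text says otherwise. The lists held 462 symbols, of which 457 were found in the gene table, 8 of them through synonyms. They cover Hox, segmentation, eye and appendage, T-box with GATA, NK and Iroquois, and neural fate genes, signalling ligands, the Polycomb and trithorax groups, the MSL complex, roX genes, sex determination, male and female germline, fat body, glue, muscle, neuronal, gut, odorant and gustatory receptor, ribosomal protein, housekeeping, pericentromeric, chromosome 4, stress and antimicrobial peptide genes. Lists were tested with Fisher's exact test where at least 3 members were eligible, with Benjamini-Hochberg adjustment over lists and directions within a comparison. The roX genes are noncoding and took no part in these tests. Genes named in the text are members of these lists, roX1 and roX2, and, in each comparison with wild-type males, the 12 lost and 12 gained genes with the largest difference between group means in covered bases, skipping any within 10 kb of a gene already taken; gene length therefore counts. Of these, 1 gene is not reported here. For females against knockout males the first 5 in each direction were taken. Regions named are the 3 longest stretches covered in both libraries of 1 group and in neither of the other after joining gaps of up to 1 kb. The wide domains were chosen after the data were seen.

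Alternatives were peaks with −log10 q of at least 3 or fold of at least 1.5, gaps of up to 1 kb joined, lists shortened to equal total length by descending −log10 p, marks at 20% or 80% of the gene body, limma on the covered percent with and without the replicate number as a block, all sequences in place of the 6 arms, other measures of overlap, and each replicate left out. The overlap of 2 comparisons with the same controls was set beside that of independent lists and beside 1000 simulated draws of unchanged groups (beta-binomial fitted to the wild-type male pair). The gene calls were run on simulated lists for knockout against wild-type males, over 13922 genes, with all peaks removed from 200 genes. Of these, 169 were marked in both simulated wild-type libraries, and all 169 were called lost. That recovery follows from the rule once the peaks are removed. It checks the computation and does not show sensitivity to a partial loss or to depth. Elsewhere there were 5 false losses and 11 false gains. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.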

Results

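The data were peak lists for H3K27me3, the histone mark laid down by Polycomb repressive complex PRC2, from chromatin immunoprecipitation and sequencing of Drosophila melanogaster larvae of the third instar. There were 3 groups: wild-type males, males lacking both roX RNAs (roX1 and roX2, the noncoding RNAs of the male-specific dosage compensation complex, MSL) and wild-type females. Each group had 2 libraries, each with its own peak list, and the 3 input samples were not used here. The lists held 5406 and 4784 peaks in wild-type males, 6327 and 6189 in knockout males, and 8896 and 10619 in wild-type females. The lists carry no read counts, so the depth of each library is unknown and a gene without a peak was not detected at that depth rather than shown to be free of the mark. The labels do not say whether replicates came from separate animals, so the spread between replicates may be technical. An exact permutation test of 2 libraries against 2 cannot give a two-sided p below 0.333. Libraries were therefore compared by whether the groups overlapped and by the size of the gap against the spread within groups.

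The Y chromosome served as a check of sex. Peaks covered 268.5 kb ± 46.6 (SD, n = 2) of Y sequence in wild-type males, 166 kb ± 0.350 in knockout males and 27.8 kb ± 3.70 in wild-type females. The roX genes themselves could not check the genotype, because they carried almost no peaks in any group. roX1 (X, 3857230 to 3862697, dm6) was covered over 7.0% of its length in female replicate 2 and over 0% in the other 5 libraries, and roX2 (X, 11579065 to 11580432) was at 0% in all 6. Overlap in bases between replicates (Jaccard index) was 0.721 in wild-type males, 0.543 in knockout males and 0.459 in females. It was 0.493 to 0.530 between wild-type and knockout males, 0.423 to 0.449 between wild-type males and females, and 0.331 to 0.374 between knockout males and females. By the share of peaks that met by 1 bp or more, the female pair was at 55.0%, against 43.4% to 46.2% between wild-type males and females.

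The comparison of knockout with wild-type males asked where H3K27me3 depends on the roX RNAs, whose proposed role outside dosage compensation concerns autosomal repression. The X chromosome showed the larger difference. Peaks covered 6.44% ± 0.293 (SD, n = 2) of X in wild-type males and 2.23% ± 0.355 in knockout males, a ratio of 0.346. On arms 2L, 2R, 3L and 3R together, coverage was 12.6% ± 0.481 in wild-type and 10.6% ± 0.945 in knockout males, a ratio of 0.840. Chromosome 4, the small and largely heterochromatic autosome, went from 18.2% ± 0.496 to 12.3% ± 1.37. Within each library, the log2 ratio of autosomal to X coverage was 0.97 ± 0.01 in wild-type and 2.25 ± 0.10 in knockout males. That gap between the groups was 1.21, against at most 0.14 between replicates (exact permutation p = 0.333, the smallest possible, two-sided). On the autosomes the groups also did not overlap, but the gap of 1.00 percentage points was smaller than the 1.34 points between the knockout replicates. Total coverage of the 6 arms was 15.5 Mb ± 0.600 in wild-type and 12.2 Mb ± 1.1 in knockout males, a log2 ratio of -0.34 that reached -0.92 among peaks with −log10 q of at least 3. At that limit the difference between the groups in log2 autosome to X ratio was 1.95, against 1.29 with all peaks.

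**Figure D1:**
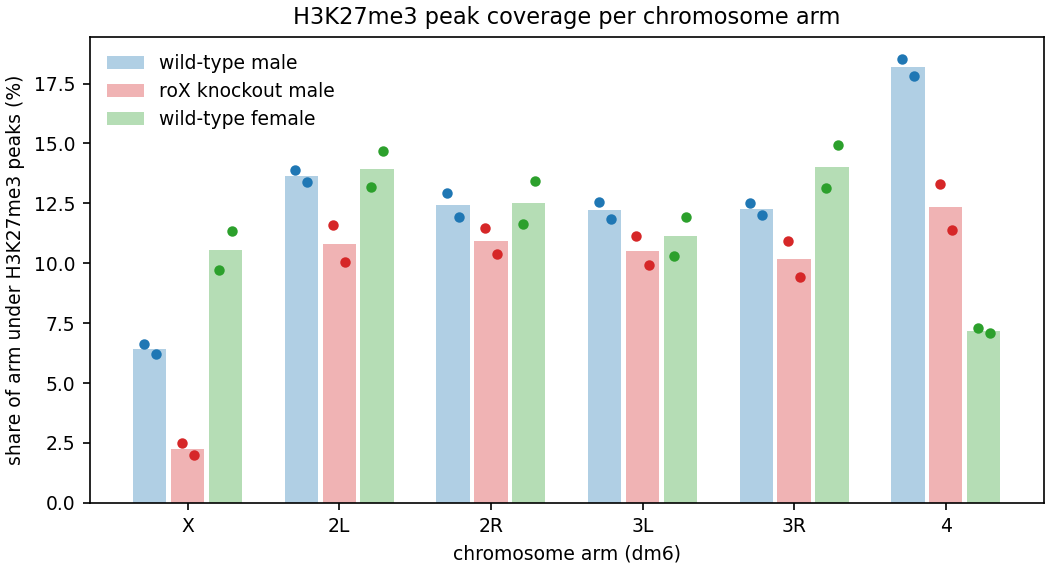
Share of each chromosome arm under H3K27me3 peaks (vertical axis, percent) by arm (horizontal axis); bars are means of 2 libraries and points are single libraries. X was at 6.44% in wild-type males, 2.23% in knockout males and 10.5% in wild-type females, while chromosome 4 was lowest in females, at 7.19%.

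Peaks wider than 20 kb were fewer in the knockout than in wild-type males, but they were fewer in females too. They numbered 145 in each wild-type male library, 94 and 84 in the knockout libraries and 97 and 88 in the female libraries. Their share of the covered length was 46.8% ± 2.34 (SD, n = 2), 28.2% ± 1.02 and 18.4% ± 2.61 in these groups. On X there were 12 and 13 in wild-type males, 0 in both knockout libraries and 14 and 13 in females. Only the absence on X was particular to the knockout. Wild-type males shared 12 X-linked and 127 autosomal domains of at least 20 kb on the large arms, a set chosen after the data were seen. In knockout males the median share of such a domain under peaks was 35.5% on X and 87.9% on the autosomes. A permutation test of that difference gave p = 1e-05, the smallest its 100000 permutations can give (two-sided, domains as units, which are not independent replicates). Coverage was under 50% in 9 of the 12 X-linked domains and in 5 of the 127 autosomal ones. The longest stretch covered in both wild-type male libraries and in neither knockout library was 21.5 kb between B-H2 and B-H1 (X, 17334535 to 17356034). The next were 15.5 kb holding CG3546 and CG12684 (X, 4558485 to 4573966) and 13 kb in the same B-H interval (X, 17364814 to 17377838). Such stretches summed to 2807 kb, and stretches with the opposite pattern to 596 kb.

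**Figure D2:**
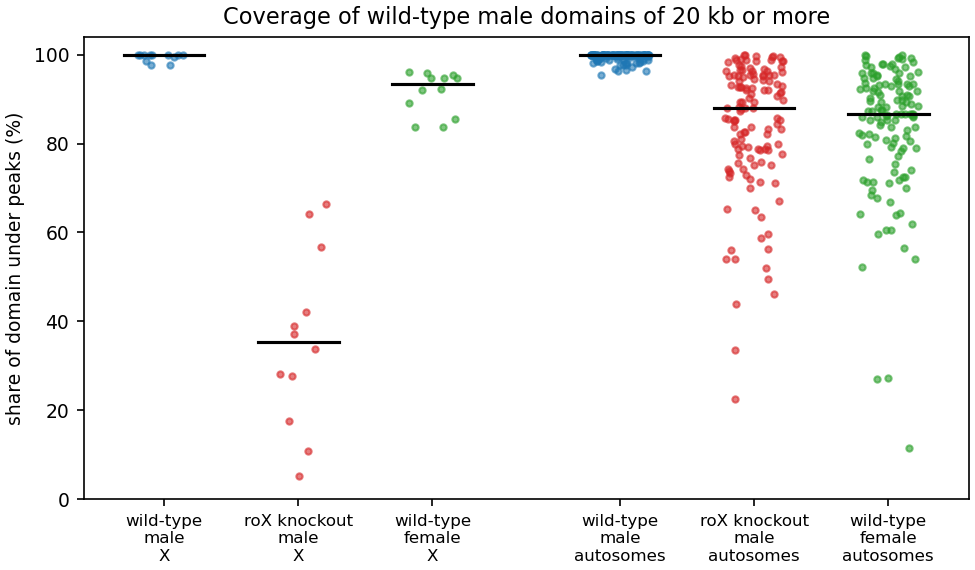
Share of each wild-type male domain of at least 20 kb under peaks (vertical axis, percent), as the mean of 2 libraries, for 12 X-linked and 127 autosomal domains in each group (horizontal axis); points are domains and black lines are medians. In knockout males the medians were 35.5% on X and 87.9% on autosomes, and in females 93.4% and 86.7%.

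At the locus of the paired homeobox genes B-H1 and B-H2, which pattern the eye and the leg, peaks covered 90.7% ± 0.187 (SD, n = 2) of the 88.7 kb from B-H2 to the end of B-H1 (X, 17314581 to 17403278) in wild-type males. They covered 5.89% ± 3.84 in knockout males and 93.1% ± 0.561 in females. At the autosomal bithorax complex, from Ubx to Abd-B (3R, 16656623 to 16972236), coverage was 98.2% ± 0.165 in wild-type males, 96.1% ± 0.935 in knockout males and 91.4% ± 0.539 in females.

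**Figure D3:**
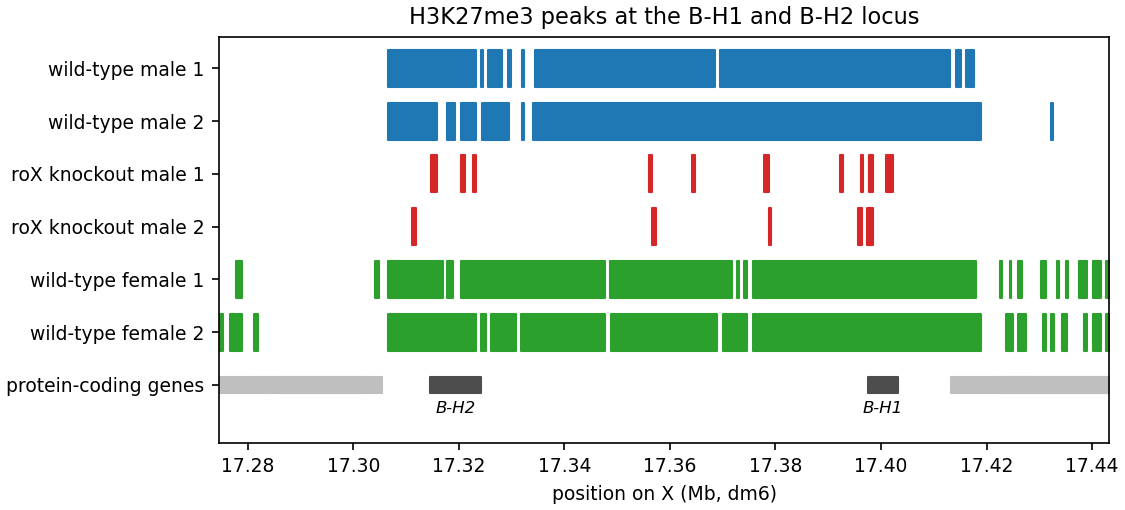
Peaks (bars) in each of the 6 libraries along X at the B-H1 and B-H2 locus (horizontal axis, Mb, dm6), with protein-coding genes in the bottom row. Peaks cover 90.7% of the interval between the outer ends of these genes in wild-type males, 5.89% in knockout males and 93.1% in females.

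**Figure D4:**
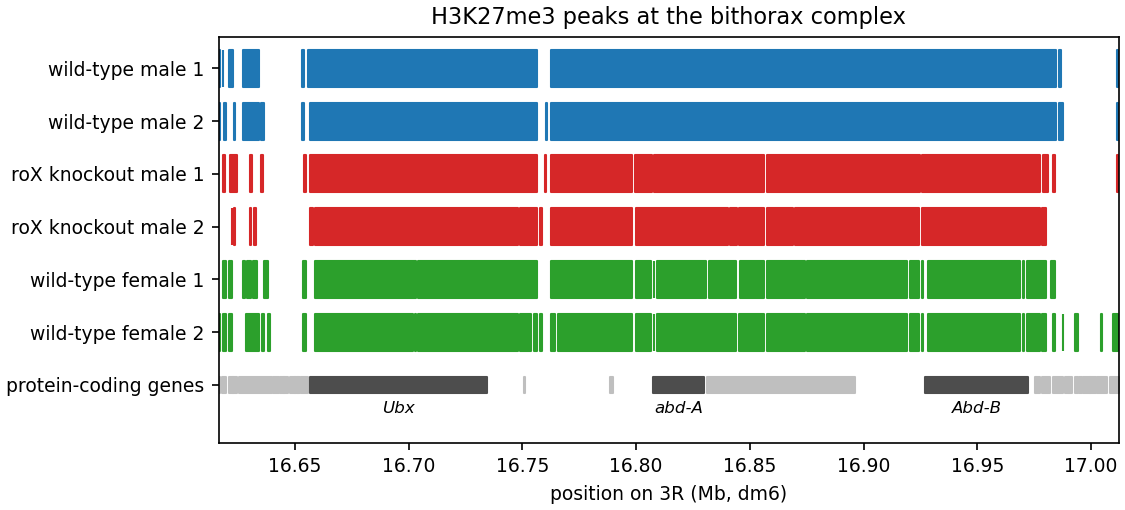
Peaks (bars) in each of the 6 libraries along 3R at the bithorax complex (horizontal axis, Mb, dm6), with protein-coding genes in the bottom row. Peaks cover 98.2% of the interval from Ubx to Abd-B in wild-type males, 96.1% in knockout males and 91.4% in females.

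A gene was called marked in a library when at least 50% of its body lay under peaks. Of 615 protein-coding genes marked in both wild-type male libraries, 162 (26.3%) were marked in neither knockout library and so lost the mark. In the other direction 10 genes gained it, and 334 were marked in all 4 libraries. By covered bases the lost genes were led by hth, the homeobox partner of Hox proteins (3R, 10507561 to 10639568), covered over 91.9% ± 0.297 (SD, n = 2) in wild-type and 36.6% ± 5.43 in knockout males. Next came the tyrosine phosphatase gene Ptp61F (3L, 1342493 to 1475257), at 71.9% ± 2.68 and 30.1% ± 5.37. The T-box gene bi, also called optomotor-blind (X, 4412856 to 4485647), was at 96.3% ± 0.0923 and 32.4% ± 3.28. The LIM homeobox gene Lim1 (X, 8756539 to 8805804) was at 100% ± 0 and 26.8% ± 7.33. Other X-linked transcription factor genes among the first 12 included disco-r (90.3% ± 0.894 and 17.5% ± 10.04), Sp1 (88.9% ± 2.56 and 11.7% ± 13.5) and lz, the Runt-domain gene of eye and blood cells (93.2% ± 0.830 and 23.7% ± 11.4). The remaining autosomal genes were grh (54.4% ± 2.78 and 22.3% ± 7.63), Lim3 (72.8% ± 4.56 and 29.9% ± 9.80), jing (61.3% ± 1.41 and 40.03% ± 7.34) and CG9380 (83.0% ± 2.90 and 44.8% ± 4.20).

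The 10 genes that gained the mark were short, from 0.288 kb to 3.20 kb. They were CAH9, CG3222, CG15873, CG31266, Ste:CG33243, Mst98Cb, CG9897, robl37BC, CG31008 and CG46270. CAH9, a carbonic anhydrase gene (3R, 27102988 to 27106184), was covered over 32.7% ± 6.5 in wild-type and 68.4% ± 3.54 in knockout males, and CG15873 (2R, 24429578 to 24430699) over 0% and 81.6% ± 1.51. Among peaks with −log10 q of at least 3, CAH9 was covered less in knockout than in wild-type males. Ste:CG33243 belongs to the repeated Stellate family, whose copies share reads, so its call is uncertain. The other 2 ways to split the 4 libraries into pairs gave at most 14 genes in 1 direction, below the 162 losses but above the 10 gains. Leaving out 1 library relaxes the rule, and the count of 162 became 252 and 191 without knockout replicates 1 and 2 and 243 and 255 without wild-type male replicates 1 and 2. The count of 10 became 46 without knockout replicate 1, 102 without knockout replicate 2 and 18 without wild-type male replicate 1. With limma on the covered percent of 4990 genes, 69 genes were lower and 4 higher at an adjusted p under 0.05, and 49 of the 162 were among the former. With −log10 q of at least 3, 151 genes lost the mark, 50 of them among the 162, and with lists of equal total length 86 did, 78 of them among the 162.

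Loss fell unequally on the chromosomes. Among X-linked genes marked in both wild-type male libraries, 28 of 51 (54.9%) lost the mark, against 133 of 558 (23.8%) on the large autosomal arms, a difference of 31.1 percentage points (Fisher's exact test, two-sided, p = 7.44e-06, genes as units). By arm the share was 20.9% on 2L, 32.8% on 2R, 26.0% on 3L and 19.7% on 3R, and 1 of 6 genes on chromosome 4. Gains were 1 of 2136 X-linked and 9 of 10875 autosomal genes (Fisher's exact test, p = 1). With 10 gains in all, too few were expected on X for this test to show a deficit there. Without knockout replicate 2 the difference in gains, X minus autosomes, was -0.826 percentage points (Fisher's exact test, p = 5.01e-06), and without knockout replicate 1 it was -0.367 points (Fisher's exact test, p = 0.00446).

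Each fixed gene list was compared with the other genes marked in both wild-type male libraries. Of those, 26.1% to 27.1% lost the mark, depending on the list. All 8 Hox genes were marked in all 6 libraries. Of 25 segmentation genes, 23 and 22 were marked in the wild-type male libraries and 19 in each knockout library; of 22 eligible genes, marked in both wild-type male libraries, the gap genes hb and Kr lost the mark. Of 25 eye and appendage patterning genes, 22 and 23 were marked in wild-type and 17 and 16 in knockout males; B-H1, B-H2, bab2, hth and Lim1 lost the mark, 5 of 22 eligible. B-H1 went from 100% ± 0 to 27.4% ± 14.5 and bab2, a gene of distal leg and abdominal patterning, from 60.5% ± 0.0557 to 28.8% ± 3.4. Of 25 genes for T-box, GATA, NK and Iroquois factors, 21 were marked in each wild-type male library and 20 in each knockout library, and bi alone lost the mark, 1 of 21 eligible. Of 25 genes for neural fate factors, 16 were marked in each wild-type male library and 12 and 11 in the knockout; grh, Lim3 and zfh2 lost the mark, 3 of 16 eligible. Of 20 signalling ligand genes, 10 and 11 were marked in wild-type and 7 and 5 in knockout males; Wnt4, the BMP gene dpp and the cytokine gene upd3 lost the mark, 3 of 10 eligible. The coverage of upd3, which is X-linked, went from 73.5% ± 6.97 to 0%, and that of dpp from 72.6% ± 3.75 to 43.7% ± 6.18. The carbon dioxide receptor genes Gr21a and Gr63a, the ovarian gene otu and the zinc finger gene jing, from the Polycomb group list, completed the listed losses. With lists of equal total length, jing, Gr21a and Wnt4 were covered more in knockout males. No list passed an adjusted p of 0.05 in either direction (Fisher's exact test per list). The lowest adjusted p was 0.684, for the T-box, GATA, NK and Iroquois list. Its genes lost the mark less often than other genes, at 4.76% against 27.1%, so any excess in that list is of genes that kept the mark. Without knockout replicate 1 that list passed, with 1 of 21 genes lost (Fisher's exact test, adjusted p = 0.0120).

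No gene of the trithorax group (15 genes), the MSL complex (6), neuronal function (18), cytosolic ribosomal proteins (60), other housekeeping functions (20) or pericentromeric heterochromatin (20) was marked in any library. Of the 16 muscle genes measured, 1 was marked in each library, and of the 13 sex determination genes 1 in every library except female replicate 2, which had 2. Of 19 Polycomb group genes 3 were marked in each wild-type male library, 2 in each knockout library and 3 and 2 in females. Of 19 odorant and gustatory receptor genes 4 and 3 were marked in wild-type males, 1 in each knockout library and 1 and 2 in females. Of 14 gut genes 4 and 3 were marked in wild-type males, 3 and 2 in knockout males and 5 in each female library. Of 9 fat body genes 1 was marked in each wild-type male library and in knockout replicate 1. Of 10 glue genes 1 was marked in each wild-type male library, 1 in knockout replicate 2 and 3 in female replicate 2. Of 14 stress genes 1 was marked, in wild-type male replicate 2, and of 16 antimicrobial peptide genes 1 was marked in each female library. Of 19 chromosome 4 genes 4 were marked in each wild-type male library, 3 in each knockout library and 1 in each female library.

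Wild-type females and wild-type males were compared to describe how the mark differs between the sexes, which differ in X number and in having the MSL complex. Coverage of X was 10.5% ± 1.15 (SD, n = 2) in females and 6.44% ± 0.293 in males, a ratio of 1.64. The pooled share of the 4 large autosomal arms overlapped between the sexes, at 12.9% ± 1.19 and 12.6% ± 0.481. Of these arms 3R alone did not overlap, at 14.0% ± 1.25 in females and 12.3% ± 0.359 in males, a gap of 0.620 percentage points against 1.77 between replicates. Chromosome 4 was at 7.19% ± 0.127 in females and 18.2% ± 0.496 in males, a gap of 10.5 percentage points against 0.702 between replicates. The log2 ratio of autosomal to X coverage was 0.29 ± 0.02 in females, so that the gap to wild-type males was 0.65 against 0.03 between replicates (exact permutation p = 0.333, the smallest possible, two-sided). Total coverage did not separate the sexes (16.7 Mb ± 1.57 and 15.5 Mb ± 0.600, exact permutation p = 0.667). Among peaks with −log10 q of at least 3, however, its log2 ratio was -0.71, against 0.11 with all peaks. Female peaks were narrower and more numerous, with 18.4% ± 2.61 of the covered length in peaks over 20 kb against 46.8% ± 2.34 in wild-type males.

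In females 64 genes lost and 142 gained the mark relative to wild-type males, and 464 were marked in all 4 libraries. The genes that lost most covered bases included 4 on chromosome 4, each for a transcription factor. Sox102F (4, 800436 to 834393) was covered over 25.1% ± 0.0937 in females and 91.0% ± 1.26 in males, and zfh2 (4, 501810 to 540874) over 26.1% ± 0.684 and 69.0% ± 2.33. The Pax genes sv (4, 1088798 to 1113317) and toy (4, 989725 to 1007922) were at 17.7% ± 0.920 and 20.6% ± 8.18 in females and at 83.9% ± 4.56 and 92.3% ± 0.268 in males. The first was CG9380, at 25.2% ± 1.78 and 83.0% ± 2.90. The others were grh, bab2, the neuropeptide gene Nplp1, the FGF receptor gene htl, the fat body gene Fbp1, rempA and AhcyL2; htl was at 37.5% ± 11.9 and 79.7% ± 6.01. The gains were led by the X-linked zinc finger gene Cph (X, 7137723 to 7241932), at 70.2% ± 4.89 in females and 45.9% ± 0.774 in males. The homeobox gene ct (X, 7608428 to 7678859) was at 61.0% ± 1.1 and 47.5% ± 0.703, slgA (X, 21374002 to 21385159) at 80.2% ± 3.23 and 38.2% ± 6.59, and the neural homeobox gene vnd (X, 582121 to 598151) at 64.9% ± 9.65 and 40.2% ± 0.560. CG3081, CG1387, CG14195 and CG2901, also X-linked, had no peak in wild-type males and lay between 67.7% ± 14.7 and 83.5% ± 11.7 in females. The autosomal gains named were tun, CG13325, Fancm and twz. Fancm, a DNA repair helicase gene, was at 78.4% ± 5.18 and 18.9% ± 5.30. The others started nearer the limit of 50%: tun was at 51.0% ± 1.16 and 44.4% ± 0.442, CG13325 at 67.7% ± 1.43 and 47.0% ± 3.45, and twz at 58.7% ± 9.15 and 41.3% ± 8.60.

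These counts depended on the calls of weak peaks. With −log10 q of at least 3, 4 genes gained and 118 lost the mark, with 3 of the 142 gains and 20 of the 64 losses among them; ct and tun then had lower, and rempA higher, mean coverage in females. The count of 142 became 582 without female replicate 1 and 357 without female replicate 2, and the count of 64 became 98, 117, 111 and 122 without female replicate 1, female replicate 2, wild-type male replicate 1 and wild-type male replicate 2. The other 2 splits of the 4 libraries gave at most 19 genes in 1 direction. With limma 345 genes were higher and 89 lower in females at an adjusted p under 0.05, including 93 of the 142 and 24 of the 64.

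None of the 51 X-linked genes marked in both wild-type male libraries lost the mark in females, against 60 of 558 (10.8%) autosomal genes (Fisher's exact test, two-sided, p = 0.00608). With 1 gene per 100 kb the difference, -10 percentage points, had p = 0.146 in Fisher's exact test; it also missed 0.05 at a limit of 20% of the gene body (Fisher's exact test, p = 0.0768) and with lists of equal total length (Fisher's exact test, p = 0.0995). Gained genes were 27 of 2136 (1.26%) on X and 115 of 10875 (1.06%) on autosomes (Fisher's exact test, p = 0.424). With lists of equal length X gains were 0.679 percentage points more frequent (Fisher's exact test, p = 0.000588), and without female replicate 2 they were rarer, at -0.426 points (Fisher's exact test, p = 0.310). Of 6 genes marked on chromosome 4 in wild-type males, 4 lost the mark in females.

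Of the fixed lists, chromosome 4 genes and gut digestive genes came nearest the threshold between the sexes, each with an adjusted p of 0.0795 (Fisher's exact test per list). Of the 4 eligible chromosome 4 genes, toy, zfh2 and sv lost the mark. Of 10 eligible gut genes, the amylase gene Amy-d and the maltase gene Mal-A1 gained it; Mal-A1 (2R, 8449664 to 8451904) went from 0% in wild-type males to 81.9% ± 2.68. No list passed in the set of all libraries, but gains passed in the ligand list at a limit of 80% of the gene body, and in the gut list with gaps of up to 1 kb joined and without female replicate 2. The other listed changes were the losses of hb, bab2, grh, Gr21a, Gr63a, the sperm gene dj, Fbp1, the glue gene Sgs5 (covered more in females with lists of equal total length) and Vha100-4, and the gain of vnd. Of 24 male germline genes 4 and 3 were marked in wild-type males and 2 and 4 in females, with 5 and 2 in knockout males. Of 14 female germline genes 3 and 2 were marked in wild-type males, 1 in each knockout library and 4 and 3 in females.

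Knockout males and wild-type females, both without a complete MSL complex, differed more than either did from wild-type males on X. They also differ in X number, so their difference on X was not tested apart from X dose. Coverage of X was 4.73 times higher in females, at 10.5% ± 1.15 (SD, n = 2) against 2.23% ± 0.355, and that of chromosome 4 was 0.583 times that of knockout males. Total coverage differed by a log2 ratio of 0.45, and by 0.21 among peaks with −log10 q of at least 3. The log2 autosome to X ratios of the groups were 1.87 apart, against at most 0.14 between replicates (exact permutation p = 0.333, the smallest possible, two-sided); at the stricter limit their means differed by -2.69 rather than -1.96. In females 232 genes gained and 15 lost the mark relative to knockout males. The gains were led by Cph (70.2% ± 4.89 in females, 3.96% ± 1.86 in knockout males), Ptp61F (65.3% ± 2.75 and 30.1% ± 5.37), ct (61.0% ± 1.1 and 0.449% ± 0.634), bi (89.3% ± 4.28 and 32.4% ± 3.28) and Lim1 (89.8% ± 1.44 and 26.8% ± 7.33). In wild-type males Cph and ct were at 45.9% ± 0.774 and 47.5% ± 0.703, under the limit of 50%. They could therefore not be called lost in knockout males, although most of that coverage was absent there. The losses were led by Sox102F (25.1% ± 0.0937 and 64.9% ± 15.2), sv (17.7% ± 0.920 and 56.3% ± 7.51) and toy (20.6% ± 8.18 and 70.4% ± 10.6), then the alkaline phosphatase gene Alp2 and CG10317.

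Gains in females over knockout males were more frequent on X, with 62 of 2170 genes (2.86%) against 170 of 11038 (1.54%; Fisher's exact test, two-sided, p = 7.14e-05). The difference of 1.32 percentage points became 0.955 without female replicate 1 and 0.475 without female replicate 2. Neither passed 0.05 in Fisher's exact test. With 1 female library left out the rule for gains is relaxed, so how far the difference depends on single libraries cannot be told from this. None of 17 X-linked and 12 of 335 autosomal genes lost the mark (Fisher's exact test, p = 1). With 17 eligible X-linked genes and so few losses, this test could not have shown a deficit on X. The gains included 4 of 8 eligible eye and appendage patterning genes, B-H1, B-H2, hth and Lim1 (Fisher's exact test per list, adjusted p = 0.000180), and 2 of 5 eligible T-box, GATA, NK and Iroquois genes, bi and vnd (adjusted p = 0.0440). Of 3 eligible chromosome 4 genes, toy and sv lost the mark (adjusted p = 0.0484). The 2 lists of gains were set against all genes unmarked in knockout males, most of them unmarked in wild-type males too. Among the 162 genes marked in both wild-type male libraries and neither knockout library, a set chosen after seeing the data, 4 of 5 eye and appendage genes gained the mark against 74 of 157 others (Fisher's exact test, adjusted p = 0.983). There the T-box list held bi alone and was not tested. An excess of eye and appendage genes beyond their being marked in wild-type males was therefore not shown. That list was not tested at 20% of the gene body, where 1 gene was eligible. Gains in 4 further lists passed only under alternatives. The ligand list passed with −log10 q of at least 3 (4 of 18 genes, Fisher's exact test, adjusted p = 8.58e-06), with lists of equal total length, at 80% of the gene body and without knockout replicate 1. The neural fate list passed under the same alternatives except equal length, the gut list at 20% and with gaps joined, and the segmentation list without female replicate 1. The T-box and chromosome 4 calls ended under several alternatives. In Fisher's exact test the T-box list had adjusted p = 0.0565 without knockout replicate 2, 0.0876 without female replicate 2, 0.138 with −log10 q of at least 3, and 0.136 and 0.250 at 20% and 80% of the gene body. The chromosome 4 list had 0.102 to 0.221 with any 1 library left out, 0.787 at 20% of the gene body and 0.0616 with lists of equal total length. Other listed gains were gt, Lim3, dpp, upd3, otu, orb and Mal-A1. With −log10 q of at least 3, 45 genes gained the mark, 26 of them among the 232, and 7 lost it. The count of 232 became 698 without female replicate 1 and 471 without female replicate 2, and the count of 15 became 40, 86, 28 and 28 without knockout replicate 1, knockout replicate 2, female replicate 1 and female replicate 2. The other 2 splits gave at most 32 genes in 1 direction, above the 15 losses.

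Of the 162 genes that lost the mark in knockout males and the 64 that lost it in females, 39 were shared, among them CG9380, grh, bab2, hb, zfh2, Gr21a and Gr63a. Independent lists of these sizes among the 615 eligible genes would share 16.9. That value takes every eligible gene as equally likely to be lost. In knockout males, however, 57.7% were lost in the 20% of genes with the lowest wild-type fold and 5.69% in the 20% with the highest. An expectation that allows for this was not computed. Simulated unchanged groups set against the same wild-type male libraries shared 6.0 on average and 14 at most in 1000 draws. The simulated lists held only 19.1 and 18.9 genes on average, so this value is chance with no effect and no reference for lists of 162 and 64. Of the 162 genes, 78 were marked in both female libraries. The lists of gained genes shared 3 (CG31266, Mst98Cb and Ste:CG33243), against 0.109 for independent lists and 5.31 for simulated unchanged groups, whose lists held 19.0 each on average, so the same holds. The 2 wild-type male libraries cannot be split into parts of 2 libraries each, and part of the excess may come from these shared controls. The shared losses numbered 16 with lists of equal total length, 89 with −log10 q of at least 3, 78 without wild-type male replicate 1, 91 without wild-type male replicate 2 and 66 without female replicate 2. The shared gains numbered 1 with −log10 q of at least 3, 8 at 20% of the gene body, 9 and 15 without knockout replicates 1 and 2, 8 and 5 without wild-type male replicates 1 and 2, and 5 without female replicate 1 and, likewise, without female replicate 2.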

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

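The tests of depth, of the single X in knockout males and of the male X background were chosen only after the results they bear on had been seen; the tests by fold of the wild-type peaks and with 1 gene per 100 kb were set beforehand. Signal outside the 6 main arms was looked at in every pair of groups and called higher where both libraries of 1 group lay above both of the other, which unchanged groups do in 1 of 3 cases by chance. Every pair differed so in each of the 3 measures below. The Y chromosome was covered over 268.5 kb ± 46.6 (SD, n = 2) in wild-type males, 166 kb ± 0.350 in knockout males and 27.8 kb ± 3.70 in females. The ribosomal DNA sequence was covered over 28.1 kb ± 3.27 in knockout males, 20.7 kb ± 0.729 in wild-type males and 15.95 kb ± 2.21 in females, and unplaced scaffolds over 421 kb ± 20.3, 321 kb ± 81.1 and 194.5 kb ± 41.2.

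In knockout males 162 genes lost and 10 gained the mark. A background level was taken from the folds and p-values of narrow autosomal peaks under an assumed Poisson model. For knockout replicate 1 it was 1.04 times that of the lower wild-type male library. The 95% bootstrap interval, 1.03 to 1.04, resampled peaks and holds no spread between libraries. Replicate 1 lay at 19.8, between the 19.1 and 20.7 of wild-type males, yet marked 564 genes against 719 and 733. Females marked 936 and 1185 genes at levels of 16.1 and 15.8. The peak caller and the use of the inputs are unknown, so this level need not follow depth. Lower depth of replicate 1 was therefore neither shown nor excluded. For replicate 2 the ratio to the lower wild-type male library was 0.758. A lower depth cannot be told apart there from a lower level of the mark, since its list holds no reads. A library-wide drop in enrichment stays open for the autosomal losses: the share lost was 57.7% in the 20% of genes with the lowest wild-type fold and 5.69% in the 20% with the highest, a difference of 52.0 percentage points, which weak enrichment would give and a real loss at weak domains might give as well. The genotype itself is the biological alternative and was not tested apart from this.

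X-linked genes lost the mark more often than autosomal genes in knockout males, by 31.1 percentage points. Weaker enrichment of X-linked genes in wild-type males is argued against as the whole cause. Within classes of 20% of genes by wild-type fold the difference was 26.4 points (stratified permutation p = 0.00018). Genes were the units there, and those of 1 domain are not independent. The classes of highest and next highest fold held 0 and 3 X-linked genes. The difference was largest in the middle class, where 56.0% of 25 X-linked and 15.8% of 95 autosomal genes were lost. In the class below, the shares were 52.9% and 39.4%, and in the lowest, with 6 X-linked genes, 83.3% and 56.4%. A few domains with many genes are argued against too. With 1 gene per 100 kb, without classes of fold, the difference was 26.7 points (16 of 28 against 64 of 210 genes, Fisher's exact test, p = 0.00936). What stays open is that the single male X gives fewer background reads than an autosome pair, so that a library-wide drop in enrichment could take X-linked peaks under the threshold first: wide X domains had a median of 35.5% in knockout males against 64.2% in the 26 autosomal domains of lowest wild-type fold, a difference of -28.8 points (permutation p = 0.00048), but the ranges overlapped and the size of the drop cannot be taken from peak lists, so this cannot be told apart from an effect of the roX deletions on X. Both deletions also lie on X, so its strain origin may differ, and no test here bears on that.

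X was covered 1.64 times more in wild-type females than in wild-type males, while the pooled share of the 4 large autosomal arms overlapped. A technical explanation is that peaks on the single male X were called against a genome-wide background. The background level implied for X peaks in wild-type males was 0.986 and 0.992 times that for autosomal peaks, so the lower dose of X was not allowed for, which is what this explanation needs. It may account for part or all of the difference between the sexes, but knockout and wild-type males both have a single X. A sex difference in the mark was not tested apart from X dose, and neither was the difference on X between females and knockout males. In knockout males the levels for X and autosomal peaks were 19.2 and 19.8 in replicate 1 and 14.0 and 14.5 in replicate 2.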

How the results depend on the processing

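The greater loss on X than on autosomes in knockout males kept its direction and stayed past the threshold under all 11 alternatives run, from 21.4 to 39.9 percentage points, with a highest p of 0.00936 in Fisher's exact test. The gap between X-linked and autosomal wide domains in knockout males also stayed past the threshold under the 6 alternatives run for it, which were chosen after seeing the data. Counts of genes were less stable, and where a value below differs from the reported one the cause was not tested unless stated. With −log10 q of at least 3, gains numbered 1 in knockout males and 4 in females against wild-type males and 45 in females against knockout males; losses numbered 118 in females against wild-type males and 7 against knockout males. Losses shared by both comparisons then numbered 89 and shared gains 1. The log2 ratios of total length became -0.92 for knockout against wild-type males, -0.71 for females against wild-type males and 0.21 for females against knockout males, and the differences in log2 autosome to X ratio 1.95, -0.74 and -2.69. The difference in gains on X in knockout males changed sign, to 0.0465 percentage points, as it did with 80% of the gene body, to 0.0749 points. At that limit of q the differences in mean covered percent changed sign for CAH9 in knockout males (-18.6), for ct (-8.94), tun (-3.05) and rempA (31.9) in females against wild-type males, and for dpp in females against knockout males (-11.2).

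With lists of equal total length, which fixes total length by construction, losses numbered 86 in knockout males and 34 in females, gains 18 and 79, gains in females over knockout males 119, and shared losses 16. The log2 autosome to X differences were 1.43 and -0.59 for knockout males and females against wild-type males. For females against wild-type males the difference on X became -7.16 points among lost and 0.679 among gained genes. Mean covered percent was then higher, by 14.1 for jing, 13.8 for Gr21a and 9.62 for Wnt4 in knockout males, and by 46.0 for Sgs5 in females. At 20% of the gene body, gains numbered 36 in knockout males, 434 in females and 504 in females over knockout males, losses in the last comparison 26 and shared gains 8; 1 list passed there, and the X difference among genes lost in females was -5.93 points, against -10 with 1 gene per 100 kb. At 80%, gains numbered 4, 45 and 98 in the same order, and 1 list passed for females against wild-type males, as it did with gaps joined. With limma, losses numbered 69 and gains 4 in knockout males, gains 345 in females, and losses 41 and gains 419 in females against knockout males.

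The labels do not say whether equal-numbered libraries share anything beyond the replicate number. The correlations of replicate differences between groups over 4990 genes were -0.0347, -0.00658 and 0.0197. With the replicate block, limma gave 22 losses and 2 gains in knockout males, 20 and 84 in females, and 7 and 154 in females against knockout males, with fewer residual degrees of freedom. Leaving out 1 library relaxes the rule for its group, so counts rose by construction: losses ranged from 191 to 255 in knockout males, 98 to 122 in females and 28 to 86 in females against knockout males, and gains from 15 to 102, 165 to 582 and 258 to 698. Shared losses ranged from 44 to 91 and shared gains from 5 to 15. Differences in gains on X ranged from -0.826 to -0.0523, -0.426 to 0.303 and 0.475 to 1.15 points, and lists that passed from 0 to 1, 0 to 1 and 1 to 4. Of 696 values of named genes under alternatives, 9 changed sign and 126 others moved by more than the SD of replicates pooled over the 2 groups. A further 56 moved by exactly that SD, which leaving out 1 library gives by construction where the other group has no spread. With the fold limit of 1.5 every reported loss and gain was kept and females gained 143 genes rather than 142 relative to wild-type males. The total over all sequences and the other measures of overlap stayed within the replicate spread. The planned promoter windows were not run, because the gene table used here gives no strand. Unknown depth limits all counts of weak peaks.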

Other observations

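The 12 X-linked domains of at least 20 kb in wild-type males, which include those at B-H1, Lim1 and bi, differed widely in what knockout males retained. The domain at the head gap gene oc, also called orthodenticle (X, 8631504 to 8662329), was covered over 64.5% and 63.7% in the knockout libraries, and that at Vsx1 (X, 5581499 to 5612158) over 41.7% and 42.5%. A domain without a named gene (X, 4575071 to 4616995) was at 12.7% and 9.02%, and that at disco-r (X, 16125915 to 16165374) at 18.2% and 17.0%. In females the same 12 domains had a median of 93.4%, against 86.7% for the 127 autosomal ones (permutation p = 0.0696). These domains were singled out after their values were seen.

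Single genes stood out against their group, also picked after the fact. The trunk patterning gene tsh (2L, 21828593 to 21837011) was covered over 100% ± 0 (SD, n = 2) in wild-type males, 35.3% ± 25.7 in knockout males and 59.4% ± 1.67 in females, so it was not called in any comparison. The engrailed gene en (2R, 11524006 to 11528210) was at 100% in all 6 libraries. The ovarian gene otu (X, 8485008 to 8489535) was at 95.3% ± 6.65 in wild-type males, 0% in both knockout libraries and 94.4% ± 7.95 in females. The Hox gene Dfd (3R, 6791836 to 6802428) was at 100% in all 6 libraries, while pb (3R, 6707800 to 6742063) was at 98.2% ± 2.51, 88.8% ± 7.41 and 83.0% ± 1.01 in wild-type males, knockout males and females.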
